A study of Homo sapiens with 7 samples.

How the data were processed

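Small RNA in saliva was profiled on Agilent human miRNA microarrays, 1 array per person, in 3 people with tongue squamous cell carcinoma (TSCC) and 4 healthy controls. Per the labels, the RNA input was 100 ng per array, the dye was Cy3 and the array covers miRBase release 19. Each array was read in 1 colour, per the file headers. The labels give each sample to a different individual, so the arrays within a group are biological replicates.

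The deposited scanner files hold intensity values per spot, which were extracted with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The processed intensity is background-subtracted and not scaled between arrays, per the file headers, and can fall below 0. The same deposited files give the software's own detection call for each miRNA and other marks per spot, such as well above background, outlier and saturated. A further deposited table gives log2 values per spot for the same 7 arrays. The notes also name R 2.15, without a step. From the values, each log2 column has the rank order of median signal minus background median of its own array (Spearman 1 on every array, against at most 0.675 with any other array) and nearly the same distribution on every array, with column medians from 3.20 to 3.30. Its direction therefore holds no open question. Rank order does not show its scale, and the exact normalisation step is inferred and not stated. No aligner, genome build or coordinates were needed. The miRNA names are those of the array design and can be old. The gene table supplied for names was not used.

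Levels were computed from the processed intensity. Control spots and spots marked as outliers were left out, spots of a probe were averaged, and the probes of a miRNA were averaged on the linear scale, which gave 2006 miRNAs from 4774 probes and 60180 spots. No probe name was shared between miRNAs. Each array was divided by its own 75th percentile over the 109 miRNAs detected on all 7 arrays. A floor was then set at the median over arrays of the lowest detected scaled level (-7.46 on the log2 scale), and log2 was taken. A log2 level of 0 is thus the array's own 75th percentile. The floor (0.00568 on the scaled level) lies below the lowest detected scaled level of the dim arrays, 0.0496 in control replicate 1 and 0.0322 in TSCC replicate 2, so the difference of a miRNA at the floor can come out too large as well as too small. Where the software detected a miRNA on no array of a group, the fold is a lower bound on the difference of these means, without an error. It was computed against each array's lowest detected level, or the miRNA's own level where that was higher.

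The 365 miRNAs detected on at least 3 of the 7 arrays, whatever their group, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). All 7 arrays entered, with no covariate. Single values per array were compared by an exact permutation test over all 35 splits of the arrays into 3 and 4 (two-sided, absolute difference of means), for which the smallest possible p is 0.0286. A per-miRNA exact permutation test was run beside limma. The control probes dmr_285 and dmr_31a were taken as labelling spike-ins and dmr_3 and dmr_6 as hybridisation spike-ins, from general knowledge of the platform. Control spots were summarised as the median per probe and then the mean over the probes of a control. This was chosen after a first summary over all spots had mixed probes of different brightness. With 3 and 4 arrays, the number of arrays limits the precision of every value.

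The 18 lists of miRNAs came from general knowledge. They cover miRNAs reported higher or lower in oral or head and neck carcinoma tissue, miRNAs typical of squamous epithelium, myeloid cells, lymphocytes, red blood cells, stroma and endothelium, skeletal muscle and exocrine gland, the let-7, miR-29 and miR-30 families, the miR-15 and miR-16 family, the clusters of miR-17, miR-20a and miR-92a and of miR-23, miR-24 and miR-27, NF-kB-induced miRNAs, the imprinted 14q32 cluster, and GC-rich or repeat-like miRNAs that are often bright with degraded or dilute RNA. Of their 214 names, 4 were not matched to a name on the array. Lists with at least 4 tested members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation beside it, and with fry.

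The miRNAs named in the text follow a rule. It takes those past the threshold, at most 12 in each direction by size of the difference, then fills up to 12 in each direction by the smallest unadjusted p. It adds the 3 brightest tested members of each list, the 8 brightest miRNAs of all, and miR-139-5p and miR-21-5p in any case. Groups, tests, lists, this rule and most of the alternatives were fixed before the data were examined. A further 4 alternatives were chosen after seeing the data: a common detection limit as floor, scaling by labelling spike-ins, leaving out the dimmest array of each group, and the array signal level as a covariate. The alternatives chosen beforehand were other scalings, other summaries of the spots, other floors and filters, other thresholds and tests, normexp background correction with an offset of 50, the deposited log2 table, and leaving out each array in turn. Normexp was to run on mean spot signals. Median spot signals were used in their place, since the files used here hold no mean signal. The offset was added before scaling. It exceeded the signal level of the dimmest array, 28.7 in processed intensity in control replicate 1. Under normexp dim miRNAs therefore lie close together, and the signs of their differences say little about direction. A block for slide and scan could not be fitted, because the headers give 1 slide and 1 scan for all arrays.

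The limma step was tested on simulated data with the means and spreads of these 365 miRNAs in 20 simulations of the comparison of TSCC with controls. Of the simulated changes, it recovered 4.50% at a log2 change of 1, 21.0% at 2, 47.2% at 3, 78.8% at 4, 88.2% at 5 and 96.0% at 6. Of its calls, 2.96% were false, and 1 of 20 simulations without any change gave a call. A simulated list of 30 members shifted by 2 was called in 20 of 20 simulations and an unshifted list in 1. The simulated miRNAs varied independently and had no floor. The 4 lists tested here had 5, 5, 4 and 41 tested members and estimated correlations of 0.43, 0.53, 0.22 and 0.04. The simulated rates of list calls therefore do not carry over to these lists.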

Results

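Saliva miRNA was measured on 7 arrays, from 3 people with TSCC and 4 healthy controls, and the design asks which salivary miRNAs differ between the groups. On the array, 586 of 2006 miRNAs were detected in at least 1 saliva sample, 1420 in none and 109 in all 7. The brightest miRNAs in both groups were miR-6089, with a mean log2 level of 4.39 ± 0.57 in TSCC (SD, n = 3) and 4.82 ± 0.75 in controls (SD, n = 4), and miR-4454, with 3.34 ± 0.99 and 4.86 ± 0.32. By the mean over all 7 arrays they were followed by miR-4516, miR-6090, miR-3960, miR-6125, miR-197-5p and miR-6087. No spot was saturated (0 on every array).

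The number of miRNAs detected per array was 399, 171 and 528 in TSCC saliva and 137, 299, 205 and 416 in control saliva. The means were 366 ± 181 (SD, n = 3) and 264 ± 121 (SD, n = 4), and the difference of 101.8 was within the spread of the arrays (exact permutation p = 0.429). The difference in miRNAs detected per array was 20.8 without TSCC replicate 3, 59.3 without control replicate 1 and 199 without TSCC replicate 2. The signal level of the arrays, taken as the 75th percentile over the 109 miRNAs detected everywhere, ran from 28.7 in control replicate 1 to 1153 in TSCC replicate 3, a 40.2-fold range. It differed 22.6-fold within the TSCC group and 15.2-fold within the control group. The groups' mean log2 signal levels were 8.23 ± 2.31 (SD, n = 3) and 6.92 ± 1.61 (SD, n = 4), a difference of 1.31 on the log2 scale (exact permutation p = 0.371). With the level taken anew over the miRNAs detected on all arrays left, the difference was 0.34 without TSCC replicate 3. It was 0.79 without control replicate 1 and 2.53 without TSCC replicate 2. Spike-in RNA added at labelling varied 1.33-fold over the same arrays and spike-in RNA added at hybridisation 1.12-fold. All TSCC arrays lay in slide row 1 and all control arrays in slide row 2 of 1 slide, so slide row and group cannot be told apart.

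**Figure D1:**
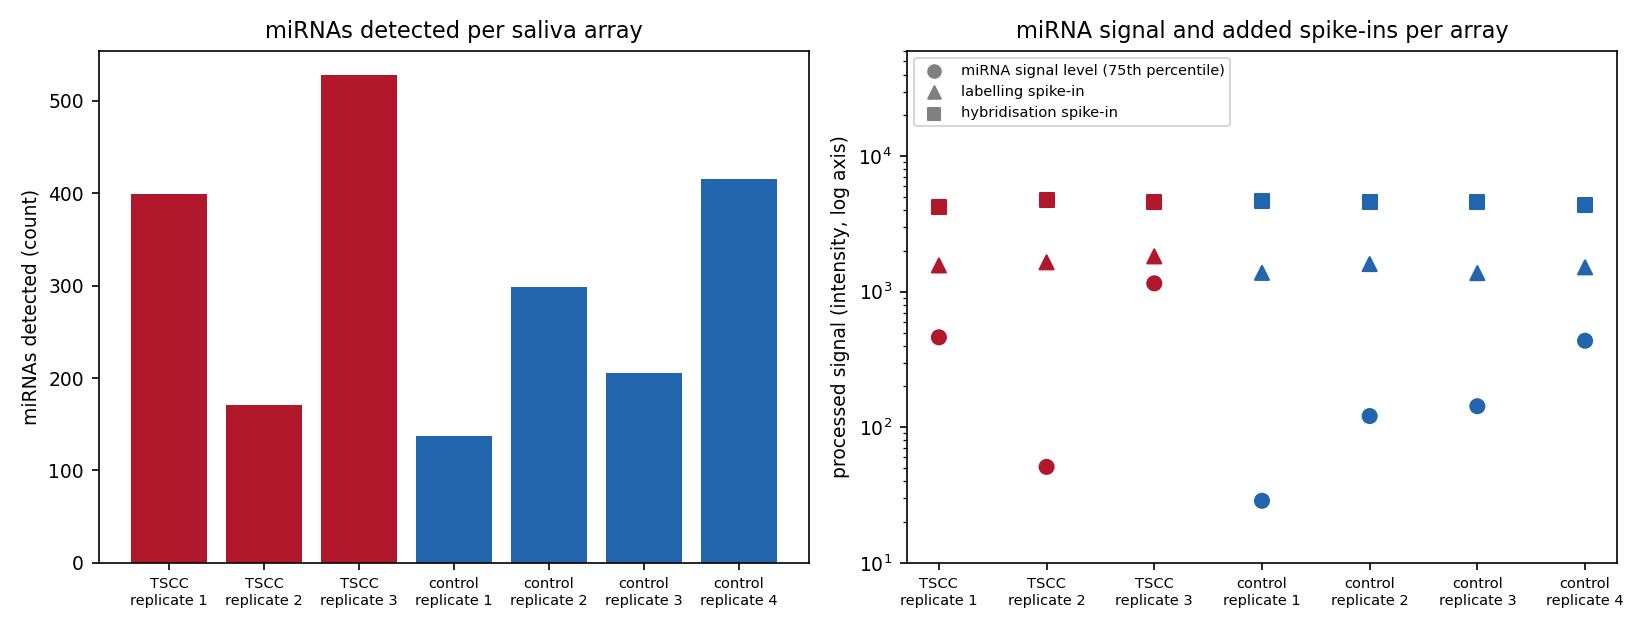
The left plot gives the number of miRNAs detected on each array as bars, with TSCC in red and control in blue. The right plot gives, on a log axis in units of processed intensity, the 75th percentile of the miRNA signal (circles) beside the labelling (triangles) and hybridisation (squares) spike-ins, where the miRNA signal spans 40.2-fold and the spike-ins 1.33-fold and 1.12-fold.

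Between TSCC and control saliva, the largest mean differences among miRNAs with an unadjusted p under 0.05 in limma were those of miR-150-3p, miR-4327 and miR-4257, whose means were lower in TSCC. For miR-150-3p the log2 difference (TSCC minus control) was -3.99 (SE 1.36), for miR-4327 -3.64 (SE 1.27) and for miR-4257 -3.49 (SE 1.17). Without TSCC replicate 2 these shrank to -2.25 (SE 1.27), -2.18 (SE 1.24) and -2.29 (SE 1.19). In the other direction stood miR-6514-3p with 3.47 (SE 1.13), miR-34b-3p with 2.99 (SE 1.11) and miR-3591-3p with 2.97 (SE 1.16). Without control replicate 1, which lay at the floor for all 3, hsa-miR-6514-3p fell to 2.55, hsa-miR-34b-3p to 2.39 and hsa-miR-3591-3p to 1.89. None of these passed the adjusted threshold in limma with Benjamini-Hochberg adjustment. The count past adjusted p 0.05 was 0 of 365, the count past 0.10 was 0, and the smallest adjusted p was 0.939. At an unadjusted p under 0.05, limma gave 13 miRNAs, 7 with a higher and 6 with a lower mean in TSCC, where chance alone gives 18.2. That count was 6 without TSCC replicate 1 and 7 without control replicate 3, but 24 without the dimmest array of each group and 22 (4 higher, 18 lower) with the signal level as a covariate. Its balance depended on single arrays, with 13 higher and 2 lower without TSCC replicate 2 and 2 higher and 10 lower without control replicate 1, and on the scaling, with 8 higher and 0 lower with no scaling and 5 higher and 0 lower with labelling spike-in scaling. It also depended on floor and background. With the common detection limit as floor it was 1 higher and 5 lower, where 1 of the 7 higher miRNAs kept an unadjusted p under 0.05, and with normexp it was 2 higher and 6 lower, where 0 of the 7 did. Those scalings also moved the median difference of all tested miRNAs from -0.15 to 0.90 and 0.73, so the sign of a smaller difference depends on the scaling. Over all tested miRNAs 153 had a higher and 212 a lower mean in TSCC, against 38 and 327 with normexp, 95 and 264 without control replicate 1 and 336 and 29 with no scaling, so turned signs in a list under these settings go with a shift of most miRNAs. The exact permutation test per miRNA gave 4 at an unadjusted p under 0.05 and 0 after adjustment. Its smallest possible p is 0.0286. After adjustment over 365 miRNAs it could give a call only if most of them reached that minimum, so this 0 says little.

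The precision was low for most miRNAs. The median SE of a log2 difference was 1.04, and the median 95% interval reached 2.19 to either side, which is a 4.56-fold difference. All SEs given are limma's moderated ones, drawn toward a spread common to all miRNAs (10th to 90th percentile 0.94 to 1.18). They can lie above or below a miRNA's own error. For miR-5100 and miR-4286 the SEs were 0.91 and 0.90, while the group SDs were at most 0.46 and 0.45. In data simulated with the spreads of these arrays, but with independent miRNAs and no floor, 21.0% of log2 changes of 2 and 78.8% of log2 changes of 4 were recovered. By size alone, 90 of the 365 miRNAs differed at least 2-fold between the group means.

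The 12 miRNAs with the smallest p and a higher mean in TSCC were miR-6514-3p, miR-34b-3p, miR-3591-3p, miR-451b, miR-4655-5p, miR-4730, miR-4254, miR-449b-3p, miR-6510-5p, miR-6076, miR-6716-3p and miR-765. Their log2 differences lay between 1.71 and 3.47. In 10 of these 12, control replicate 1 stood at the floor. Without that array they lay between 0.95 and 2.55, with the common detection limit as floor between 0.61 and 2.21, and with normexp between -0.069 and 0.64. For miR-6514-3p the mean log2 level was -1.74 ± 1.29 in TSCC (SD, n = 3) and -5.21 ± 1.99 in controls (SD, n = 4), and the software detected it on 3 of 3 TSCC and 2 of 4 control arrays. miR-34b-3p and miR-449b-3p are arms of the related miR-34 and miR-449 hairpins, known for their part in multiciliated cells. Whether this bears on their levels in saliva was not tested, and miR-34a-5p differed by -0.47 (SE 0.95). Both were highest on TSCC replicate 1 and, among controls, on control replicate 2. The same held for miR-6514-3p and miR-3591-3p, which are outside these families, so the pattern over the arrays is not particular to them. miR-449b-3p differed by 2.11 (SE 1.07). With normexp background correction hsa-miR-449b-3p came near 0 at -0.069, as did hsa-miR-4655-5p at -0.021, hsa-miR-4254 at -0.043 and hsa-miR-765 at -0.045. The normexp offset brings dim miRNAs close together, so these signs say little about direction.

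The 12 with the smallest p and a lower mean in TSCC were miR-4257, miR-150-3p, miR-4327, miR-4484, miR-4286, miR-5100, miR-193a-5p, miR-4454, miR-4758-5p, miR-92b-3p, miR-760 and miR-4787-3p. For 5 of them, every TSCC value lay below every control value. These were miR-4257, miR-4484, miR-4286, miR-5100 and miR-4454, with log2 differences of -3.49, -2.37, -2.13, -2.02 and -1.52. Over the 12 the median difference was -2.05. It shrank to -0.61 with normexp, -0.76 with no scaling and -0.96 with labelling spike-in scaling. All 12 stayed lower there, with the difference nearest 0 at -0.12, -0.11 and -0.30. With the common detection limit as floor all 12 also stayed lower, with a median of -1.77. The difference nearest 0 was then -0.080, that of miR-193a-5p. No miRNA had every TSCC value above every control value (0 of 365). Chance alone gives groups without overlap for 5.71% of miRNAs, or 20.9 of 365, against the 5 found. miR-5100 had a mean log2 level of -1.60 ± 0.46 in TSCC (SD, n = 3) against 0.42 ± 0.43 in controls (SD, n = 4). The miRNA miR-193a-5p was detected on 0 of 3 TSCC arrays and 3 of 4 control arrays. Its lower bound on the difference of these means was 2.38-fold, lower in TSCC, and carries no error. Its log2 difference was -2.09, with a limma confidence interval from -4.20 to 0.025 (limma adjusted p = 0.994). A lower level in TSCC is therefore not established for it.

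Calls appeared under a few other settings, and they were always among miR-150-3p, miR-4327 and miR-4257, each lower in TSCC. The 3 shared a similar profile over the arrays. In that order, their log2 levels were highest on control replicate 2 (2.775, 5.534 and 2.751) and lowest on TSCC replicate 2 (-7.461, -3.692 and -5.417). Their calls are therefore not 3 independent results. With limma's trend and robust options, 2 miRNAs passed, miR-150-3p and miR-4257, both at an adjusted p of 0.0165. With normexp background correction, 2 passed, miR-150-3p at an adjusted p of 0.0268 and miR-4327 at 0.000398. Leaving out TSCC replicate 1 gave 3 calls, TSCC replicate 3 gave 2 and control replicate 1 gave 2. In these 3 settings and with normexp, limma gave all 3 miRNAs the same SE within a setting (1.19, 1.11, 1.11 and 0.46). These calls therefore rest on a spread shared across miRNAs, not on each miRNA's own. With no filter the SEs were 1.95 for miR-150-3p, 1.42 for miR-4257 and 1.71 for miR-4327. The unadjusted limma p there was 0.095, 0.057 and 0.086. Leaving out TSCC replicate 2, or control replicate 2, 3 or 4, gave 0. Without TSCC replicate 2 the differences of the 3 lay between -2.18 and -2.29 (limma adjusted p = 0.607 for each), and without control replicate 2 between -2.64 and -3.09 (limma adjusted p = 0.995 for each). Over all settings tried, the adjusted p of miR-150-3p and of miR-4257 ran from 0.0165 to 1, and that of miR-4327 from 0.000398 to 1.

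**Figure D2:**
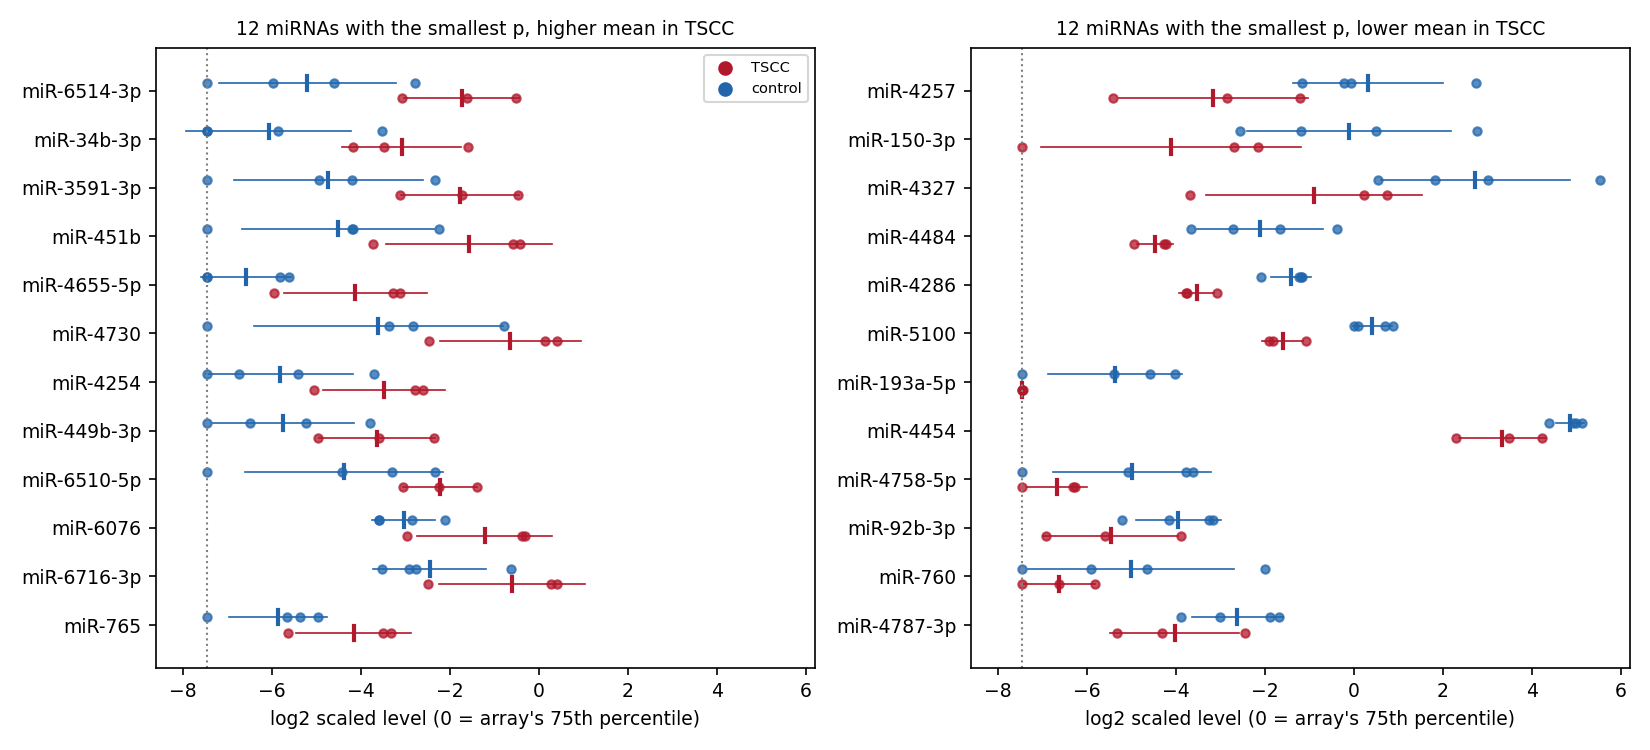
Log2 scaled levels per array (0 is the array's 75th percentile) of the 24 miRNAs with the smallest p, 12 with a higher mean in TSCC on the left and 12 with a lower mean on the right. Points are arrays (TSCC red, n = 3; control blue, n = 4), thick ticks are means, thin lines are 1 SD to either side and the dotted line is the floor at -7.46; the points of miR-4257, miR-4484, miR-4286, miR-5100 and miR-4454 do not overlap between the groups.

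No miRNA was detected on all 3 TSCC arrays and on none of the controls (0), and none on all 4 control arrays and on no TSCC array (0). Allowing 1 array of the detecting group to miss it, 25 miRNAs were detected in TSCC only and 1, miR-193a-5p, in controls only. The rule is unequal, since it needs 2 of 3 TSCC arrays but 3 of 4 control arrays. In 23 of the 25, the detecting arrays were TSCC replicates 1 and 3, the 2 brightest of all 7. By detection the order differs, since control replicate 4 showed 416 miRNAs and TSCC replicate 1 showed 399. Of the list members among the 25, miR-654-3p and miR-758-3p lie in the imprinted 14q32 cluster. The list does not hold every arm of that cluster. miR-411-3p, the other arm of the listed miR-411-5p, was also among the 25.

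Among miRNAs reported higher in oral or head and neck carcinoma tissue, 6 of 24 were detected on some array and 5 could be tested. Of these, 4 had a higher and 1 a lower mean in TSCC, and none passed the threshold (0 adjusted over all tested miRNAs and 0 adjusted over the list alone; 0 at an unadjusted p under 0.05 in limma). The widely studied oncogenic hsa-miR-21-5p was detected on 2 of 3 TSCC and 2 of 4 control arrays, with a log2 difference of 1.19 (SE 0.99, exact permutation p = 0.200). Its 95% interval ran from -0.89 to 3.26, and with normexp background correction the difference came near 0 at -0.056. miR-184 differed by 0.64 (SE 1.32) and miR-1246 by -0.07 (SE 1.05). The 5 tested members had a median difference of 0.48 (camera adjusted p = 0.483). Without control replicate 1 the median was -0.18 (2 higher, 3 lower), with normexp -0.056 (0 higher, 5 lower), with no scaling 1.49 (5 higher, 0 lower) and with the signal level as a covariate -0.36 (2 higher, 3 lower). Among miRNAs reported lower in such tissue, 7 of 25 were detected and 2 tested, miR-34a-5p with -0.47 (SE 0.95) and miR-125b-5p with 0.95 (SE 0.96). miR-139-5p was detected on 0 of 7 arrays.

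Over the whole array 29.2% of miRNAs were detected on at least 1 array. The share was above this for the myeloid, squamous epithelial, red blood cell, lymphocyte and exocrine gland lists and below it for the stromal and skeletal muscle lists. Of the myeloid list, 6 of 11 members were detected, and miR-223-3p, abundant in neutrophils, was the only member detected on all 7 arrays. Its mean log2 level was 0.56 ± 1.83 in TSCC (SD, n = 3) and 0.41 ± 1.25 in controls (SD, n = 4), a difference of 0.16 (SE 1.08). In the same list miR-23a-3p differed by -0.12 (SE 0.99) and miR-27a-3p by -0.10 (SE 1.03). The squamous epithelial list had 7 of 15 members detected and 1 tested, miR-205-5p, with a difference of 1.15 (SE 1.24). Among red blood cell miRNAs 6 of 12 were detected and 3 tested, with miR-16-5p at 0.52 (SE 1.00), miR-92a-3p at -0.64 (SE 1.12) and hsa-miR-25-3p at -0.96 (SE 0.96; 0.059 with no scaling). Lymphocyte miRNAs were detected for 4 of 10, with miR-29a-3p at 0.05 (SE 1.04) and miR-342-3p at -0.31 (SE 0.99). Stromal and endothelial miRNAs were detected for 2 of 13, and both were tested, with miR-22-3p at -1.40 (SE 1.10) and miR-125b-5p at 0.95 (SE 0.96). Exocrine gland miRNAs were detected for 6 of 7 and skeletal muscle miRNAs for 1 of 7, but none on enough arrays to be tested (0 and 0). In each of these lists the count past the threshold was 0 over all tested miRNAs and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 in limma.

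The miRNA families gave the same counts of 0 past the threshold, adjusted over all tested miRNAs or adjusted over the list alone, with 0 at an unadjusted p under 0.05 in limma. In the let-7 family, regulators of differentiation, 6 of 9 members were detected and let-7b-5p alone was tested, at 0.79 (SE 0.93). In the cluster of miR-17, miR-20a and miR-92a and its paralogs, 9 of 14 members were detected, and of the 5 tested 3 had a higher and 2 a lower mean (1 and 4 with the 75th percentile over all miRNAs, 5 and 0 with no scaling, 0 and 5 with normexp, 2 and 3 without control replicate 1), with hsa-miR-20a-5p at 1.06 (SE 0.95; -0.051 with normexp background correction). Detection covered 3 of 7 members of the miR-15 and miR-16 family, where miR-15b-5p differed by -0.04 (SE 0.97), and 5 of 8 of the miR-23, miR-24 and miR-27 clusters, where miR-24-3p differed by 0.93 (SE 1.04). The miR-29 family had 3 of 6 members detected and 1 tested, the miR-30 family 4 of 7 and 0 tested. Of the NF-kB-induced list 2 of 8 were detected, and miR-21-5p was the 1 tested.

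In the imprinted 14q32 cluster, 9 of 33 members were detected and all 4 tested members had a higher mean in TSCC, by between 0.08 (SE 1.07) for miR-485-3p and 0.79 (SE 1.31) for miR-494, with miR-134 at 0.54 (SE 1.12). Their mean difference of 0.43 turned to -0.10 with normexp background correction and to -0.17 without control replicate 1, and was 1.28 without TSCC replicate 2. With the signal level as a covariate it was -0.25 (1 higher, 3 lower) and without TSCC replicate 1 -0.018 (1 higher, 2 lower). With no scaling it was 1.68 (4 higher, 0 lower). With normexp 0 of the 4 were higher, and 1 without control replicate 1. None passed the threshold (0 over all tested, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 in limma).

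The GC-rich or repeat-like miRNAs had the most complete detection of the 18 lists. All 42 members were detected on some array and 31 on all 7, and they held between 32.8% and 66.7% of the positive miRNA signal of an array (median 58.0%). The lowest share was that of control replicate 2 alone, and every other array had at least 55.3%. Of 41 tested, 21 had a higher and 20 a lower mean in TSCC (40 and 1 with no scaling, 14 and 27 with normexp, 18 and 23 without control replicate 1), 1 (miR-150-3p) had an unadjusted p under 0.05 in limma, and 0 passed the threshold over all tested or adjusted over the list alone. Among the brightest, miR-4516 differed by -0.55 (SE 0.98), miR-6090 by -0.44 (SE 0.91) and miR-6089 by -0.43 (SE 0.93).

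Of the 18 lists, 4 had enough tested members for camera, and 0 passed. The camera adjusted p was 0.483 for the carcinoma-higher list, 0.483 for 14q32, 0.533 for the GC-rich list and 0.628 for the miR-17 cluster. With an estimated correlation they were 0.735, 0.735, 0.735 and 0.790, so there was no call to keep. The mean of the GC-rich list was -0.04, while its median was 0.02 and its camera direction was upward. Before adjustment camera gave 0 lists under 0.05, and fry gave 0, with p from 0.608 to 1.00 for a shift in one direction and from 0.671 to 0.956 for mixed changes. List calls arose under a pair of settings. Restricted to miRNAs detected on all 7 arrays, the GC-rich list passed (adjusted p = 0.0301, 1 list tested; adjusted p = 0.149 with an estimated correlation), with a median of -0.05 against -0.41 for all miRNAs in that test. With no filter 3 lists passed, let-7 (adjusted p = 0.000239), the miR-17 cluster (adjusted p = 0.0137) and the GC-rich list (adjusted p = 6.51e-06). With an estimated correlation none of the 3 held (adjusted p = 0.575, 0.315 and 0.269).

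**Figure D3:**
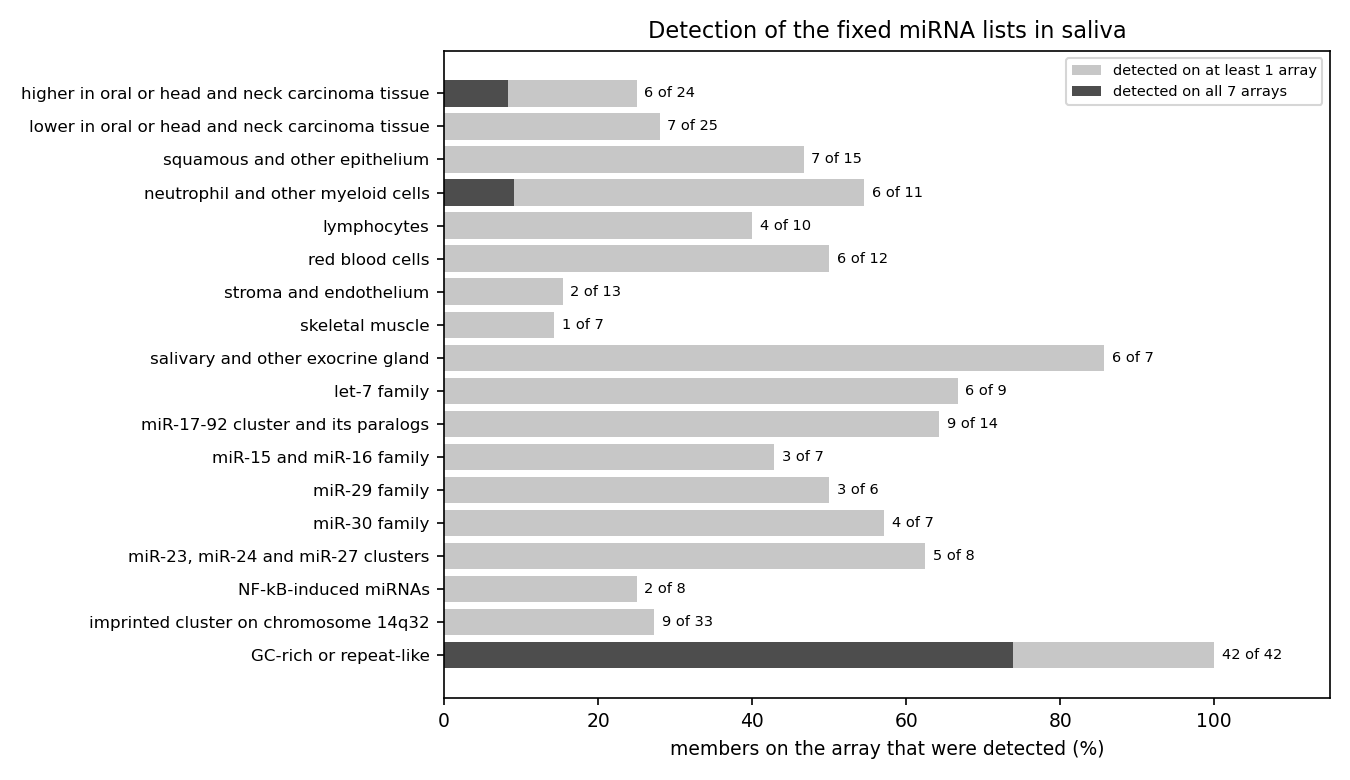
For each of the 18 lists, the share of members on the array (horizontal axis, %) that were detected on at least 1 array (light bars, with the counts beside them) and on all 7 arrays (dark bars). The GC-rich list has 42 of 42 members detected on some array and 31 on all 7, and the cell type lists have at most 1 on all 7.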

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

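The tests of labelling and hybridisation, of group as the source of the signal range, of the relation between corner spots and signal level, of slide row, of scaling and of single arrays were chosen after the values they rest on had been seen. For scaling and single arrays, the standard error was also added to the rule after a first result, which made both readings more cautious. The counts over splits of the arrays were set up before their results were seen, though the split count with trend and robust options was chosen once its calls were known.

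The signal level of the arrays spanned 40.2-fold, and the dimmest array of each group showed the fewest miRNAs of its group, 171 in TSCC and 137 in controls. The spike-in signals given in the file headers, for labelling and for hybridisation, spanned at most 1.88-fold, which argues against the efficiency of those steps as the main cause. Both header signals were highest on the brightest arrays, TSCC replicates 1 and 3 and control replicate 4, so a smaller part stays open. The hybridisation spike-in from the spots did not follow this order. It was lowest on TSCC replicate 1 (4229) and control replicate 4 (4367). Group as the whole cause is argued against by the smaller of the within-group ranges, 15.2-fold. The amount and integrity of small RNA in each saliva sample remain open and were not tested. Among the control spots, hur_1 ran from 24.2 in control replicate 1, the dimmest array, to 23330 in TSCC replicate 3, the brightest. For hur_2 these values were 27.5 and 25413. What these spots report is not stated, and their relation to the signal level was not tested.

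Corner control spots were brighter on every TSCC array than on any control array, in data that no comparison uses. The lowest TSCC array had an intensity of 113 and the highest control array 44.5, with means of 174 and 22.6 (exact permutation p = 0.0286, the smallest possible; Benjamini-Hochberg adjusted p = 0.400 over the 14 kinds of control spot). Their relation to the signal level of the 7 arrays was weak (Pearson r = 0.309, permutation p = 0.485; Spearman rho = 0.214, permutation p = 0.662; r = -0.0955 without the 2 arrays farthest from the median; 1 relation computed), and 7 arrays are too few to exclude it. Slide row cannot be told apart from group, since 0 slide rows held both. A difference in the saliva RNA itself stays open, as untested.

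The miRNAs miR-150-3p, miR-4257 and miR-4327, lower in TSCC, were the only miRNAs past the adjusted threshold in any limma setting tried. They shared a similar profile over the arrays, highest on control replicate 2 and lowest on TSCC replicate 2. They are thus not 3 independent results. The calls with normexp and with 1 array left out used an SE shared by the 3 miRNAs. Scaling may contribute. With no scaling or spike-in scaling, the difference nearest 0 among them was -1.88 (SE 2.13), too imprecise to decide. Leaving out 1 array at a time, the lowest of the 3 differences came nearest to 0 at -2.29 (SE 1.19), so a single array as the source is not excluded beyond the error. Chance remains open too: the 2 calls with trend and robust options were reached in 6 of the 35 splits of the arrays, the real one included, with up to 62 calls. A biological difference between TSCC and control saliva stays open, as untested beyond limma.

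The counts themselves were also set against the other splits of the 7 arrays. For the 13 miRNAs with an unadjusted p under 0.05, 15 of 35 splits, the real one included, gave as many, with up to 125, so chance is not excluded for that count. The counts of 0 (miRNAs past the threshold, lists past the threshold and miRNAs seen in one group only) are reached by all 35 splits whatever the data, so they say nothing about chance. Their highest values in another split were 45, 3 and 78. The split with 45 calls set the 3 arrays with the fewest detected miRNAs (at most 205), 1 TSCC and 2 control, against the other 4 (at least 299). It was the 1 split of 35 with any call, and it sorts the arrays by detection. A structure of the samples was not tested apart from array brightness and the floor. Values at the floor may contribute to its calls, since at least 15.1% of tested miRNAs lay there on each of the 3 arrays and at most 6.30% on each of the others.

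In the control group, 1 array stood apart for 2 of the 55 values looked at, where chance gives about 1 in 20 or 2.75. For miR-4286 the gap to the nearest array was 0.926 of the group's range, with the lowest log2 level at -2.08 and the next at -1.22. For miR-125b-5p it was 1, since 1 control array had -6.05 and the others lay at the floor of -7.46. The labelling spike-in dmr_285 was also higher on every TSCC array, with 2074 on the lowest TSCC array and 2067 on the highest control array.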

How the results depend on the processing

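The common floor, spike-in scaling, the omission of the dimmest array of each group and the signal-level covariate were chosen after the data were seen. Over 31 alternatives, the count of 0 miRNAs past the threshold moved to 2 with normexp, 2 with trend and robust options and 13 at an unadjusted p under 0.05. Leaving out 1 array gave 0 to 3 (3 without TSCC replicate 1, 2 without TSCC replicate 3, 2 without control replicate 1), and every miRNA that passed the adjusted threshold was lower in TSCC. The array-weights fit stopped before it converged, so its values are approximate. The count of 0 lists moved to 1 among miRNAs detected on all 7 arrays and to 3 with no filter. The count of miRNAs seen in one group only moved from 0 to 26 when 1 array could miss, to 27 without the dimmest array of each group, and to 0 to 23 with 1 array left out (23 without TSCC replicate 2). The cause was not tested, apart from fewer arrays having to share a call. The differences in miRNAs detected per array and in array signal level kept their sign in every alternative, with 20.8 to 199 miRNAs and 0.34 to 2.53 (log2) when 1 array was left out. The signal level was then taken over the miRNAs detected on all arrays left. With so few arrays left, the permutation test of those values could not reach the threshold, so it says nothing there.

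With no scaling the median difference of all tested miRNAs was 0.90 and with spike-in scaling 0.73, against -0.15, so directions of small differences depend on the scaling. With no scaling hsa-miR-25-3p turned to 0.059. With normexp, hsa-miR-4655-5p turned to -0.021, hsa-miR-4254 to -0.043, hsa-miR-449b-3p to -0.069, hsa-miR-765 to -0.045, hsa-miR-20a-5p to -0.051, hsa-miR-21-5p to -0.056 and the 14q32 list to -0.10, and that list ran from -0.17 (without control replicate 1) to 1.28 (without TSCC replicate 2) with 1 array left out. With normexp the offset brings dim miRNAs close together, so those turned signs say little about direction. Other causes were not tested. Of 1329 values of named miRNAs in alternatives, 116 changed sign, in all but the 7 named here from a difference within 1 SE of 0, and 11 passed the threshold.

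With the replicate number as a replicate block over the 6 arrays that share numbers, 0 miRNAs and 0 lists passed, as without it. The numbers share only a name: deviations of same-numbered arrays correlated at -0.53, -0.19 and 0.29, and not every array correlated best with its own number. The block for slide and scan was not run, with 1 slide and 1 scan. Signal over background limits the dim arrays, where 36.4% of tested miRNAs lay at the floor in control replicate 1 and 21.9% in TSCC replicate 2.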

Other observations

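The test of the 25 miRNAs was written before its result was seen. These were detected on 2 of 3 TSCC arrays and on no control array. In 23 of the 25, the detecting arrays were TSCC replicates 1 and 3. These arrays were also the 2 brightest of all 7, with signal levels of 461 and 1153, against 435 in control replicate 4, the next brightest. Control replicate 4 nevertheless showed more detected miRNAs than TSCC replicate 1, with 416 against 399. Brightness was not tested apart from group. With 26 miRNAs in both directions for the real groups, 12 of the 35 splits of the arrays, the real one included, gave as many, with up to 134, so chance is not excluded.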
